A study of Mus musculus with 6 samples.

How the data were processed

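PARE libraries were made from polyadenylated RNA of adult mouse brain, lung, liver, kidney, ovary and spleen (BALB/c background, 1 library per tissue), per the labels' protocols. An RNA adaptor was ligated to 5'-monophosphate ends, the RNA was reverse transcribed from an oligo(dT) primer and amplified by PCR, the enzyme MmeI trimmed each product to a short tag next to the adaptor, and tissue barcodes and further PCR preceded sequencing on the Illumina Genome Analyzer, per the labels' protocols. The tags were aligned with Bowtie to the mouse genome build mm9, per the submitters' processing notes. The Bowtie version, its mismatch setting and other filters are not given in the sources used here.

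Each deposited table lists, per the labels and the accompanying description by the authors, 1 line per distinct tag sequence with its location, strand, the tag sequence and its read count. The deposited score in these tables is a display density for a genome browser and not a measurement: it equalled 70 per read, with a ceiling of 999 from 13 reads on, in 100% of lines. Read counts per sequence, as the authors deposited them, were used as tag counts, and their totals were 36981 in brain, 547818 in lung, 86396 in liver, 179728 in kidney, 32895 in ovary and 51867 in spleen. Tags of 20 or 21 nt made up 99.6% of the total. Sequences of tags on the minus strand were found to be written in reference orientation, by comparison with tags of the plus strand over 4613 shared bases (99.6% identical as written), and were complemented. The 5' end of a tag was taken as its first base on the plus strand and its last base on the minus strand, counted from 1.

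Although the tables are of uniquely aligned tags, some sequences are listed at 2 locations, and these (9.73% of the entries in brain, 9.98% in lung, 8.62% in liver, 9.71% in kidney, 11.2% in ovary and 17.2% in spleen) were left out. The unique tags that remained gave the depths stated in the results, and levels are given as their counts scaled to a total of 1000000 per library (CPM). No tag was listed on the mitochondrial chromosome, so no tag was left out on that ground. Tags of mitochondrial RNA listed at similar nuclear sequences were not looked for.

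No genome or gene annotation of mm9 was used, and coordinates were not converted between builds. Gene names, annotation classes, positions along transcripts and the medians of gene lists, marker lists of cell types among them, were therefore not analysed here. As planned for this case, tags were summed in strand-specific windows of 2 kb, named by their mm9 coordinates. Choices of windows, minimum counts, tests and naming rules were made before the data were examined, except those described as chosen afterwards.

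Libraries were grouped by the tissue in the labels. With 1 library per tissue, comparisons between tissues are ratios of CPM with exact conditional binomial 95% intervals, and shares carry exact Clopper-Pearson intervals and single levels exact Poisson intervals. A count of 0 was taken to allow 3 counts. A window was called led by a library when that library had at least 20 tags and the lower bound of its ratio over the second highest library exceeded 1. The naming rule took, for each library, the 5 windows with the largest such lower bound, the 5 windows with the most tags and the 3 dominant ends with the most tags. It further took the 10 microRNA precursors and the 5 microRNA-directed sites with the most tags. A dominant end had at least 20 tags and at least 50% of the tags of its window. Correlations used log2 CPM with a pseudocount of 1, over windows with at least 10 tags in the 6 libraries together.

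MicroRNA loci were found by matching 102 mature mouse microRNA sequences, written from general knowledge after the files had been examined and not checked against a database, to deposited tags over at least 16 nt. This gave 94 loci of 79 microRNAs, and other microRNAs were not analysed here. The precursor test compared tags within 1 nt of the first base after a 3' arm microRNA with other positions within 60 nt of the mature arm, mature starts included, by a one-sided exact binomial test whose p-value treats tags, or distinct ends, as independent. An annotation of hairpins was intended for this test, and the sequence matches took its place. For microRNA-directed cleavage, the first 9 nt of each tag and 11 nt upstream, rebuilt from overlapping tags, were compared with nt 2 to 21 of 101 microRNAs, allowing 2 mismatches. The same search was run with 20 sets of microRNAs shuffled with their dinucleotide content kept. Ends within 120 nt of a matched microRNA locus on the same strand were left out of it. Leaving out both strands, with a locus of miR-196b added, was chosen after the data had been seen. B1 and B2 repeats and the 5' end of 18S ribosomal RNA were likewise matched to sequences written from general knowledge, the repeats with up to 4 mismatches. Base composition before the 5' end needs a genome and was not analysed here.

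Alternatives covered the unit counted (tags, distinct ends, the deposited score), thinning to 29213 tags, merging of ends within 2 nt, window widths of 1 and 5 kb, minimum counts of 10 and 50 or none, pseudocounts of 0.1 and 10, the tolerance at precursor ends, mismatches allowed, and each library left out in turn. Scaling alternatives were the total without the 10 largest windows and a trimmed mean of M values over windows, trimming 30% of M and 5% of A values on each side. The latter multiplied depths by 1.64 in brain, 1.49 in ovary, 1.19 in spleen, 0.818 in kidney, 0.747 in liver and 0.566 in lung. These are shifts of log2 depth between -0.82 in lung and 0.71 in brain, and log2 levels shift by as much in the opposite direction. The shallowest libraries, brain, ovary and spleen, had factors above 1, and lung, the deepest, had the smallest. Only windows with a tag in both a library and lung enter the factors, so an effect of depth on them was not separated. Keeping the tags listed at 2 locations was added after the data had been seen, as were the comparison of a leading library with every other one, the search with 9 nt, the range of 55 to 80 nt searched after 5' arm microRNAs and the share of ends with AATAAA.

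The procedures were tested on simulated data. With no difference between libraries, 2 of 730 simulated windows were called led. The simulated counts were independent, so the simulations do not cover the extra spread of PCR reads. The 200 windows raised by a known fold were drawn only from those with many tags. Raised 5-fold, 90.5% were recovered in a library of the lung's depth, 79% at the liver's and 31% at the ovary's. Raised 10-fold, 100%, 100% and 81% were recovered. The site search recovered 150 of 150 planted sites and none among the other simulated sequences. The planted sites lay within its mismatch limit, so this checks only that the search runs as written. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots Matplotlib 3.10.9.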

Results

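Parallel analysis of RNA ends (PARE) was applied to polyadenylated RNA of 6 adult mouse tissues of BALB/c background. By the design of the method, each tag marks the 5' end of a polyadenylated RNA that carried a 5' monophosphate. Whether every tag came from such an RNA was not tested. Such ends arise by endonucleolytic cleavage, by removal of the cap or in the course of decay, whereas capped transcripts are not ligated. The survey asked which 5'-monophosphate ends are present in brain, lung, liver, kidney, ovary and spleen. Each tissue was represented by 1 library, so no tissue has a replicate and no test between tissues was made. Uniquely listed tags numbered 33382 in brain, 493121 in lung, 78952 in liver, 162270 in kidney, 29213 in ovary and 42939 in spleen. They fell on 449338 distinct 5' ends, and the lung library was 16.9 times as deep as the ovary library. Levels are tag counts scaled to 1000000 unique tags per library (CPM). A count of 0 therefore allowed up to 6.08 CPM in lung, 18.5 in kidney, 38.0 in liver, 69.9 in spleen, 89.9 in brain and 102.7 in ovary. Intervals are exact 95% intervals that cover counting error only, since PCR reads are not independent molecules, except for those named next. The 95% intervals of median G+C differences come from resampling windows. That of the spleen share weighted by G+C is a normal approximation. The share of tags at the 10 strongest ends was 10.2% in brain, 6.33% in lung, 10.3% in liver, 10.4% in kidney, 10.1% in ovary and 5.12% in spleen. A single end, at position 24619958 of chromosome 1 and described below, gave 7.57% of the kidney tags and 3.795% of the brain tags, and without it the shares were 3.31% in kidney and 6.78% in brain.

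A primary microRNA transcript is opened by the nuclease Drosha, which frees the hairpin and leaves a polyadenylated 3' fragment that starts at the first base after the hairpin. Tags clustered at that base. Around 41 loci whose mature microRNA forms the 3' arm of the hairpin, 1059 of 1492 tags (71.0%, interval 68.6 to 73.3) lay within 1 nt of the first base after that arm. Tags spread evenly over the positions searched, within 60 nt of the mature arm, would have put 2.10% there. The excess was 33.8-fold and rested on 18 loci with a tag at the predicted end. It was present in each library alone, with 9 of 21 tags in brain, 840 of 1129 in lung, 16 of 23 in liver, 102 of 200 in kidney, 55 of 71 in ovary and 37 of 48 in spleen. Loci with a tag at that end numbered 5 in brain, 18 in lung, 2 in liver, 12 in kidney, 9 in ovary and 3 in spleen. In liver and spleen the excess thus rests on few loci, and miR-142a alone gave 31 of the spleen tags. Counting each distinct end once, 26 of 85 ends lay there (30.6%, interval 21.05 to 41.5; one-sided exact binomial p = 3.6e-23). Most of the other tags began within 1 nt of the first base of the mature microRNA, and without these, an exclusion chosen after the data had been seen, the share was 1059 of 1122 (94.4%).

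Another 50 loci had a mature microRNA of the 5' arm and no listed one of the 3' arm, so the end of the hairpin was not fixed by a mature sequence. In these loci 5698 tags began 55 to 80 nt after the first mature base, against 12 tags in the next stretch of the same width (ratio 475, interval 272 to 919). Most of the 5698 tags came from few loci, with 3314 after miR-122, 1376 after let-7b and 579 after let-7f, each within 1 nt of its strongest end. Counted once each, the distinct ends numbered 41 and 6 (ratio 6.83, interval 2.88 to 19.7). This range was chosen after the tag positions had been seen.

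**Figure D1:**
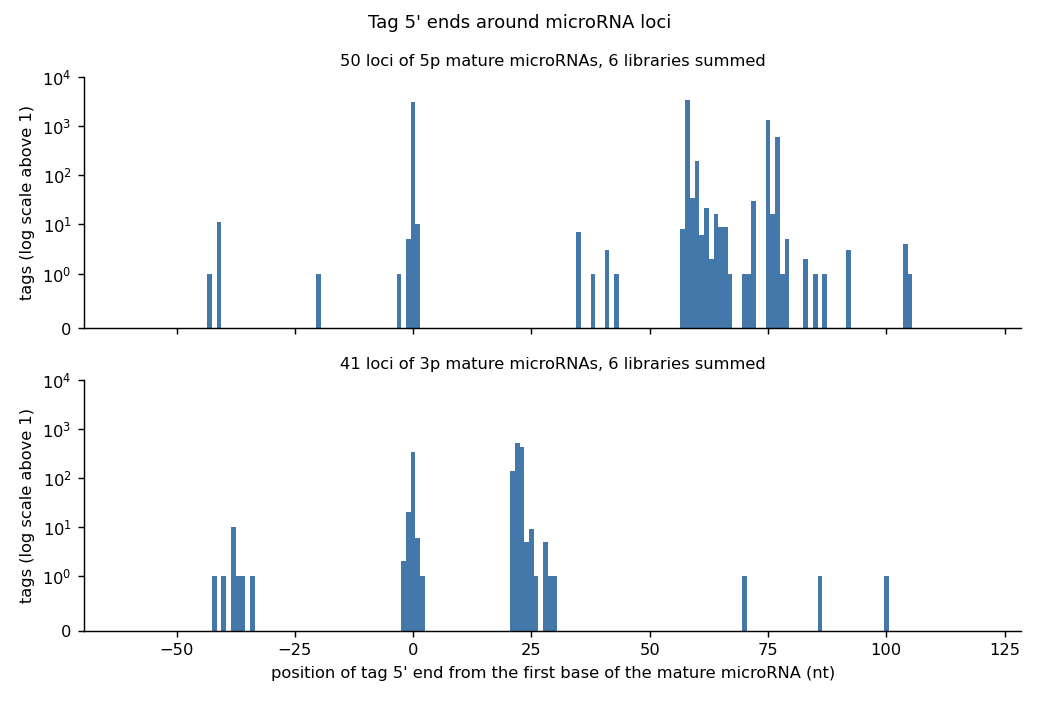
Number of tags (y axis, logarithmic above 1) by the position of the tag 5' end relative to the first base of the mature microRNA (x axis, nt), for 50 loci with a 5' arm microRNA only and 41 with a 3' arm microRNA, 6 libraries summed. Bars at 0 are tags that start with the mature microRNA, and the right-hand clusters hold the 5698 tags 55 to 80 nt after 5' arm starts and the 1059 tags just after 3' arms.

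The precursor ends with the most tags differed between the libraries. Counts and CPM at precursor ends are sums within 1 nt of the stated position. For 5' arm microRNAs that position is the one with the most tags 55 to 80 nt after the mature start, so it was picked from these data. The end after the miR-122 hairpin, the abundant microRNA of hepatocytes, lay on chromosome 18 at position 65408578 (mm9 coordinates throughout, plus strand) and held 2798 liver tags, or 35439 CPM. Kidney was second at 2095 CPM (ratio 16.9, interval 15.1 to 18.99). The end after miR-145a, a microRNA of smooth muscle, at position 61807482 on the minus strand of the same chromosome, reached 1814 CPM in ovary and 222 in kidney (ratio 8.18, interval 5.26 to 12.9). No tag was found there in brain, liver or spleen. The end after miR-214, on the plus strand of chromosome 1 within 1 nt of position 164153591, had 958 CPM in ovary against 142 in lung (ratio 6.75, interval 4.19 to 10.6). The end after miR-126a, an endothelial microRNA, at position 26446944 of chromosome 2 (plus strand), was highest in lung with 614 CPM and 303 tags. Ovary followed with 137 CPM from 4 tags (ratio 4.49, interval 1.73 to 16.6).

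Other precursor ends, also counted within 1 nt of the stated position, did not separate the 2 highest libraries. The let-7b precursor end at position 85537830 of chromosome 15 (plus strand) had 2465 CPM in ovary and 2182 in lung (ratio 1.13, interval 0.877 to 1.43), and 163 in spleen. The let-7f precursor end at position 48633202 of chromosome 13 (minus strand) had 988 CPM in lung and 958 in ovary (ratio 1.03, interval 0.704 to 1.57). The end after miR-142a, a microRNA of blood cells, at position 87570428 of chromosome 11 (plus strand) had 722 CPM in spleen and 659 in lung (ratio 1.10, interval 0.732 to 1.59). Its other libraries lay between 59.9 CPM in brain and 205 in ovary. The ends after miR-146a, miR-29c and miR-29b completed the 10 precursors with the most tags, with 77, 61 and 47 tags over the 6 libraries. With depths scaled by a trimmed mean of M values, the ratio of the same libraries was 0.430 for let-7b and 0.523 for miR-142a, below 1, and that for let-7f was 2.71. It was 4.49 for miR-145a, 2.57 for miR-214 and 11.8 for miR-126a, each still above counting error. The shares of all tags at precursor ends were 3.62% in liver (interval 3.49 to 3.75), 0.760% in ovary (0.664 to 0.866), 0.571% in lung (0.550 to 0.593), 0.438% in kidney (0.406 to 0.471), 0.198% in spleen (0.158 to 0.245) and 0.168% in brain (0.127 to 0.218). The liver share rested on miR-122: without its end it was 0.0760% (interval 0.0580 to 0.0978), and that of kidney was 0.228% (0.205 to 0.252). With the trimmed mean of M values the shares of all precursors were 4.85% in liver, 1.01% in lung, 0.535% in kidney, 0.511% in ovary, 0.167% in spleen and 0.102% in brain, so that the order of ovary, lung and kidney depends on scaling.

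**Figure D2:**
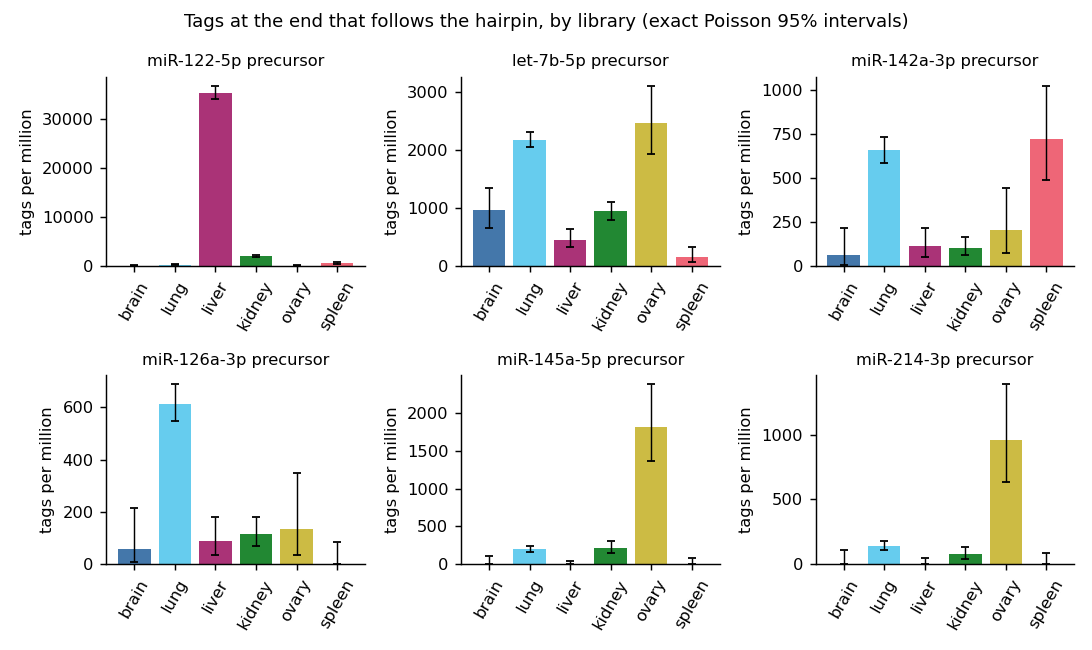
CPM (y axis) within 1 nt of the end after 6 microRNA hairpins in the 6 libraries (x axis), 1 library per tissue. Bars are values and lines are exact Poisson 95% intervals; the miR-122 end was highest in liver (35439), the miR-145a and miR-214 ends in ovary (1814 and 958) and the miR-126a end in lung (614).

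Argonaute proteins can slice a transcript that pairs almost fully with a microRNA, and the 3' fragment then starts opposite nt 10 of the microRNA. One end with many tags met this description. It lay at position 89365137 of chromosome 8 (minus strand), opposite nt 10 of miR-151-5p, and held 1097 tags. The site TCTAGACTGTGAGCTCCTCG differs from full pairing with nt 2 to 21 of the microRNA by T21A, where positions count from 1 at the microRNA's 5' end and bases are given on the microRNA strand. Tags at this end amounted to 1981 CPM in lung, 685 in ovary, 481 in kidney, 270 in brain, 139 in liver and 46.6 in spleen, and lung exceeded ovary 2.89-fold (interval 1.86 to 4.76). Of the 1265 tags within 50 nt of the site, 86.7% (interval 84.7 to 88.5) began at this base. The strongest of the neighbouring ends, 2 nt upstream, held 109 tags.

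**Figure D3:**
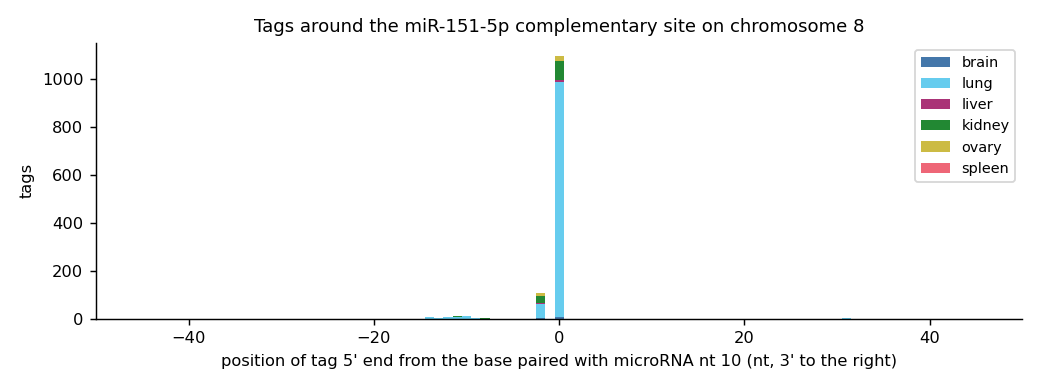
Tags (y axis) by the position of their 5' end relative to the base paired with nt 10 of miR-151-5p on chromosome 8 (x axis, nt, within 50 nt on both sides), stacked by library. The bar at 0 holds 1097 of the 1265 tags, 977 of them from lung.

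A further end opposite nt 10 of miR-151-5p, at position 115486797 of chromosome 4 (plus strand, site ACTAGACTGTGAGCTCCTTG, G3A, a G-U wobble pair), held 9 tags, but an end 2 nt upstream held 65. The last end with at most 2 mismatches, at position 52180140 of chromosome 6 (plus strand, site CCAACAACAGGAAACTACCT, miR-196a-5p, A12C), had 1 kidney tag. On the opposite strand there, 63 kidney tags with the sequence TAGGTAGTTTCCTGTTGTTGG began at position 52180149. They read as miR-196b, so this site lies antisense to a microRNA locus and its pairing follows from that. The 3 ends compare with a mean of 0.1 ends and at most 1 over 20 sets of microRNAs shuffled with their dinucleotides kept. Their tags, 1107 in all and 127 without the lung library, come mostly from the strongest end. Without the site antisense to miR-196b 2 ends remain, both opposite miR-151-5p, and their reads are partly alike beyond the paired bases too. Shuffled microRNAs need not have related copies in the genome. The shuffled sets therefore cannot tell slicing from pairing through a shared sequence origin, which was not tested. With up to 3 mismatches there were 5 ends, the added ends holding 4 tags (miR-146a-5p, chromosome 13, position 34009940) and 1 tag (miR-151-5p, chromosome 4, position 45392494). The bases upstream of the tag could be read from overlapping tags for 183060 ends (40.8% of those searched). When pairing was asked only of the first 9 nt of the tag, which needs no upstream bases, 269 ends matched against a shuffled mean of 249.7 (range 187 to 348), and 5 of the 20 shuffled sets gave as many. Kidney had the largest ratio of the 6 libraries, with 88 ends against a shuffled mean of 62 (1 of the 20 sets gave as many). By tags the sum was 1559 against a mean of 403.7, and 462 without the strongest site, which 6 of the sets reached.

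The libraries differed widely in the regions that gave tags. The genome was divided into windows of 2 kb on each strand, since no gene annotation of mm9 was used. In 957 windows with at least 20 tags in the leading library, that library exceeded the second highest by more than counting error. Liver led 271 of them, kidney 235, lung 185, spleen 184, brain 62 and ovary 20. The led windows held 46.2% of the liver tags, 29.5% of the spleen tags, 26.1% of the kidney tags, 20.8% of the lung tags, 10.5% of the brain tags and 7.91% of the ovary tags. A total of 835 windows also exceeded every other library, or the limit of its count of 0. The lung number depended most on scaling: it was 663 with the trimmed mean of M values and 315 without the ovary library. The factors of this scaling were largest in the shallowest libraries and smallest in lung, the deepest, so an effect of depth is not separated from it. With this scaling ratios over lung are divided by 2.89 for brain, 2.63 for ovary, 2.09 for spleen, 1.44 for kidney and 1.32 for liver. The ratios of the 30 leading windows named here stayed above counting error with this scaling, but not all did by distinct ends. Counting each distinct end once, 650 of the 957 windows were still led by the same library above counting error, and spleen led 27.

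In lung, a single window on the minus strand of chromosome 19 (9158001 to 9160000) took 6.68% of the library, 66793 CPM against 1989 in liver (ratio 33.6, interval 28.7 to 39.5). Its tags lay on 323 ends over the 6 libraries, and by distinct ends the lung to liver ratio was 0.654. The window at 70920001 to 70922000 on the minus strand of chromosome 14 followed with 9701 lung tags (19673 CPM, 29.9-fold over liver, interval 22.8 to 40.0). The window next to it from 70922001, one on chromosome 6 from 72264001 (plus strand) and one on chromosome 19 from 9162001 (minus strand) led by 105-fold, 37.5-fold and 26.6-fold over liver. The interval of the first of these, with 1 liver tag, ran from 18.8 to 4155.

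In liver, the window at 90904001 to 90906000 on the plus strand of chromosome 5 held 7022 tags, or 8.89% of the library. Its level of 88940.1 CPM was 14.7 times that of spleen (interval 13.0 to 16.7). The window with the miR-122 precursor end, from 65408001 on chromosome 18, was second with 2994 tags, followed by 2041 tags from 20280001 on the minus strand of chromosome 7, 1315 from 103110001 on the minus strand of chromosome 9 and 1014 from 22898001 on the plus strand of chromosome 16. By the lower bound of the ratio, the window from 81762001 on the minus strand of chromosome 3 came first, with 192 liver tags and 8 kidney tags (49.3-fold, interval 24.5 to 116). A window on the plus strand of chromosome 1 from 173156001 had 633 liver tags and led kidney 26.6-fold (interval 19.8 to 36.3). The remaining named windows began at 107582001 on chromosome 8, 108274001 on chromosome 11 (both plus strand) and 112740001 on chromosome 7 (minus strand), at 144-fold, 34.5-fold and 34.3-fold.

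In kidney, adjoining windows on the minus strand of chromosome 6 were prominent. The window from 133802001 held 5115 kidney tags, 16.6 times the lung level (interval 15.4 to 17.8), and that from 133800001 held 2569, 9.04 times the lung level (8.36 to 9.77). The window from 54722001 on the plus strand of chromosome 11 had 2601 kidney tags on a level 6.44 times that of lung (6.02 to 6.90). The largest lower bound belonged to a window on the minus strand of chromosome 7 from 126620001, with 81 kidney tags on 75 ends over all libraries and 3 lung tags (82.1-fold, interval 27.1 to 406). No tag fell there in brain, liver, ovary or spleen. Windows from 66762001 on chromosome 15 and 107142001 on chromosome 8 (both minus strand) and from 126410001 on chromosome 2 (plus strand) had 40, 43 and 30 kidney tags, against 1, 2 and 1 in lung.

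In ovary, 1123 tags fell in a window on the minus strand of chromosome X (50406001 to 50408000), 25.2 times the lung level (interval 23.0 to 27.7). Almost all of them began at position 50406452, which lies 1052 nt downstream of the first base of miR-322-5p. The window from 57874001 on the plus strand of chromosome 9 had 93 ovary tags, 5 kidney tags, 1 brain tag and 1 spleen tag (103-fold over kidney, interval 42.7 to 326). Windows from 98656001 on chromosome 3, 51750001 on chromosome 9 and 65058001 on chromosome 1, all on the minus strand, led by 38.9-fold, 7.84-fold and 22.8-fold, the last over 2 spleen tags (interval 5.797 to 196.5).

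In brain, the window from 120090001 on the plus strand of chromosome 9 had 29 tags on 27 ends over all libraries and 2 lung tags, a 214-fold ratio (interval 54.2 to 1853). The window from 94912001 on the minus strand of chromosome 1 had 43 brain tags, 6 lung tags and 1 kidney tag (106-fold over lung, interval 44.9 to 304). Windows from 107934001 and 126662001 on chromosome 10 (minus strand) had 22 brain tags each, and that from 113032001 on chromosome 12 (plus strand) had 33. In each of these 5 windows the liver, ovary and spleen libraries had no tag, which their depth allows up to the limits given above.

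In spleen, the window from 60972001 on the plus strand of chromosome 18 held 1168 tags, 2.72% of the library and 11.2 times the lung level (interval 10.3 to 12.1). The window from 110974001 on the minus strand of chromosome 7 held 13834 CPM in spleen and 7594 in lung (ratio 1.82, interval 1.67 to 1.99), but the ratio was 0.870 with the trimmed mean of M values, so the leading library depends on scaling. The window from 35332001 on the plus strand of chromosome 17 had 405 spleen tags, 35 lung tags and 8 liver tags (93.1-fold over liver, interval 46.8 to 217). On the plus strand of chromosome 19, 51 spleen tags and 1 lung tag fell in the window from 58756001 (586-fold, interval 100.5 to 23582). Windows from 50690001 on chromosome 12 and 38090001 on chromosome 1, both on the minus strand, had 83 and 50 spleen tags, on 2 ends and 1 end over all libraries. The strongest reads, TTTAAAACCTGAAAAAAAAA and TAATAAAATCTTGAACAAAA, end in runs of A. A window from 54670001 on chromosome 9 (minus strand) had 42 spleen tags and 4 lung tags (121-fold, interval 43.8 to 463), and its strongest read, TAACAAGAACAAAGAAAAAA, ends in such a run too.

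**Figure D4:**
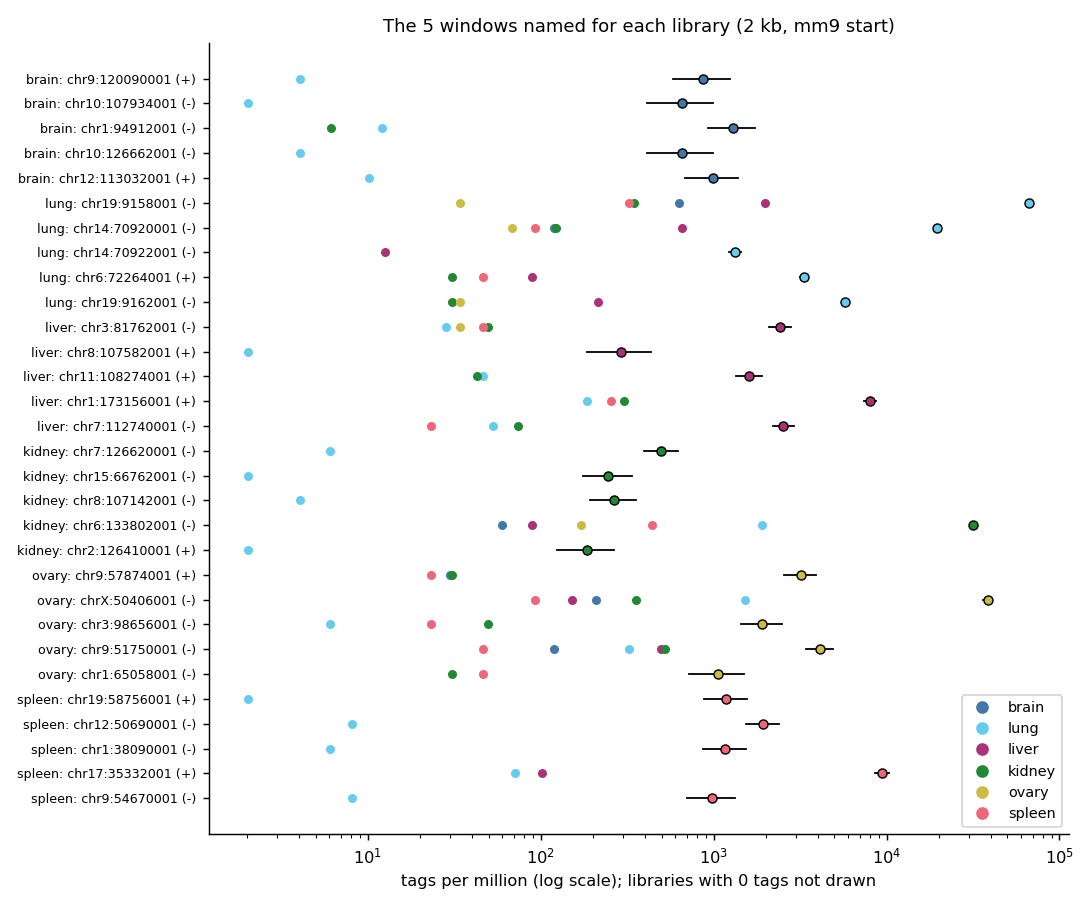
CPM (x axis, logarithmic) in the 6 libraries for the 5 named windows of each library (y axis, mm9 start and strand), points being libraries and black lines the exact Poisson 95% intervals of the leading library. Libraries without a tag are not drawn; the ratio of the leading to the second library was at least 7.84 in each.

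Single positions dominated some windows. At 390 ends, counted per library, at least 20 tags made up at least 50% of the tags of their window in that library: 197 in lung, 70 in kidney, 43 in spleen, 39 in liver, 25 in ovary and 16 in brain. These were 250 distinct positions, of which 181 qualified in 1 library and 4 in all 6. Where a window could be compared with other libraries, the same end was the strongest in at least 1 of them in 284 of 298 cases (95.3%). For the spleen ends this share was 80.6%. Positions that qualified in more than 1 library were counted for each and agree by definition, which raises these shares. Without the lung library the number was 193, and with all libraries thinned to the smallest it was 133.

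The end at position 80808871 of chromosome 10 (minus strand, read AGCCCCTTCCCCTGCGCCTTT) was among the strongest in all libraries, with 10582 tags. It held 8969 lung tags, 99.8% of its window there, and all 202 brain, 316 liver and 230 spleen tags of its window. The end at position 24619958 of chromosome 1 (minus strand) was the strongest in kidney with 12279 tags, and its window reached 75824 CPM in kidney, 38254 in brain and 19 tags in spleen. Nearly all its reads differed at 1 base from 1 common sequence. At position 31161459 of chromosome 19 (plus strand, read AATTTCGGTTGGGAAAAAAA) brain had 970 tags, and its window held 34899 CPM in brain and 7256 in lung (ratio 4.81, interval 4.50 to 5.14). The end at position 82084451 of chromosome 1 (minus strand) gave 307 of the 308 brain tags of its window, which lay 37.9-fold above lung (interval 30.6 to 47.2). In kidney the second strongest dominant end, with 957 tags, was the first base of mature let-7b at position 85537755 of chromosome 15, and the third lay at position 29469087 of chromosome 17 (minus strand) with 727 tags. Position 39979944 of chromosome 17 (plus strand) had 3195 lung tags and 228 ovary tags. It lies 3354 nt upstream of a listed location of the 5' end of 18S ribosomal RNA, on the same strand. Position 62416576 of chromosome 11 (plus strand) was the strongest dominant end of spleen with 393 tags. Of the 250 positions, 22 lay within 5 kb of a microRNA locus and 19 within 200 nt of one.

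Of all distinct ends 407547 occurred in 1 library and held 58.4% of the tags. Of these 89.8% had 1 tag and so could not occur in another library; of the 83216 ends with at least 2 tags, 49.8% occurred in 1 library. The 151 ends found in all 6 libraries held 10.4% of the tags. With all libraries thinned to 29213 tags, shared ends were expressed as a share of the library with fewer distinct ends. Lung and spleen had the largest share, 7.15% of the spleen ends (interval 6.78 to 7.53). Brain and kidney had the smallest, 2.72% of the kidney ends (2.51 to 2.94). By number, brain and liver shared fewer ends, 558 against 609 for brain and kidney. Across 12337 windows, which are not independent replicates, the Pearson correlation of log2 CPM (pseudocount 1) ranged from 0.083 for kidney and spleen to 0.391 for liver and kidney and 0.392 for lung and ovary. With thinned libraries the kidney and spleen value was -0.056.

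The spleen library differed from the others in base composition. G+C made up 31.3% of the bases at its distinct ends, against 44.8% in liver, the lowest of the other libraries, and 49.6% in kidney. The polyadenylation signal AATAAA lay in 30.1% of the spleen ends (interval 29.6 to 30.7), in 7.34% of the liver ends (7.11 to 7.59), 5.43% in lung (5.35 to 5.52), 4.54% in brain (4.30 to 4.79), 4.12% in ovary (3.87 to 4.38) and 2.33% in kidney (2.24 to 2.42). Its most frequent position was the first base of the tag in every library. Weighted by tags the share was 38.2% in spleen and 8.82% in lung. Tags ending in a run of 6 A made up 5.12% of the spleen ends (interval 4.85 to 5.39) and at most 0.309% elsewhere, in brain. Weighted by tags the shares were 5.69% in spleen and 3.801% in brain, where the end with 970 tags on chromosome 19 is of this kind. In 541 windows with at least 10 tags in both libraries, spleen tags had a lower G+C content than lung tags, with a median difference of -9.82 percentage points (interval -10.96 to -8.79). The size depended on the library compared: it was -13.25 points against kidney, -6.16 against brain, -5.49 against liver and -4.66 against ovary, with each interval below 0. Spleen tags also lay on average nearer the 3' end in 86.7% of the windows shared with lung, and in 77.8% to 89.5% of those shared with the other libraries.

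**Figure D5:**
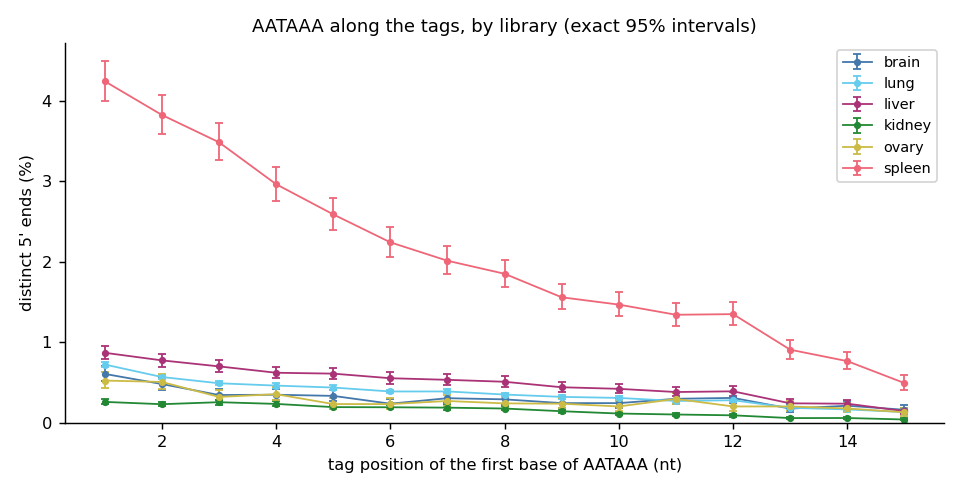
Share of distinct 5' ends (y axis, %) whose tag has AATAAA starting at each tag position (x axis, nt), by library. Points are shares and lines exact 95% intervals; in spleen the share fell along the tag from 4.24% at the first base, and lay above the other libraries at every position.

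G was rare as the first base of a tag in every library. It began 7.52% of the distinct ends in spleen and 10.1% in kidney, the lowest and highest of the 6 values, while its median share at tag positions 2 to 20 was 17.5% and 26.3% in the same libraries. T was the most common first base of distinct ends in liver with 42.5%, lung with 33.7%, ovary with 33.4% and kidney with 31.7%, and A in spleen with 39.8%. In brain T, A and C, at 30.8%, 30.1% and 30.1%, did not differ by more than counting error. Weighted by tags, A led in brain with 36.7% and in kidney with 34.8%, and in lung A and T lay at 32.8% and 32.6%. Without the end at position 24619958 of chromosome 1, whose common sequence begins with A, T led in kidney with 32.2% against 29.5% for A, T was above A in lung with 33.0% against 32.1%, and A still led in brain with 34.2%. Pairs of ends 1 to 18 nt apart on the same strand, the libraries pooled, were counted by distance. Their number fell at every step, from 87639 at 1 nt to 39072 at 18 nt, without a rise at multiples of 3 nt. Distances that leave 0, 1 or 2 after division by 3 held 31.4%, 35.5% and 33.1% of the pairs. The steady fall alone makes these shares unequal, so they cannot show or exclude a 3 nt period.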

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

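The comparison of strands was chosen after the result was seen, and the weighting by base composition before.

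Tags listed at 2 locations were left out of the comparisons, but they carry signal in every library. They made up 3599 entries in brain, 54697 in lung, 7444 in liver, 17458 in kidney, 3682 in ovary and 8928 in spleen, and they drew attention because tables of unique tags would hold none. The 5' end of 18S ribosomal RNA is among them, with 2696 tags listed at 2 locations. In 100% of the 30843 such reads the locations lay on opposite strands, which is consistent with uniqueness having been judged separately on each strand. The share was highest in spleen, at 17.2% against at most 11.2% elsewhere, and weighting the spleen tags to the G+C distribution of the lung tags lowered it to 14.4% (interval 13.9 to 14.8), so base composition could account for only part of the difference. A difference of tissue stays open and was not tested, since spleen is 1 library.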

How the results depend on the processing

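Keeping tags listed at 2 locations, weighting AATAAA shares by tags, comparing each leading library with every other one, leaving out mature starts or microRNA loci on both strands, the stretch after 5' arm microRNAs with its counts by distinct end and with hairpins of both arms, the 9 nt site search, leaving out the end at 24619958 on chromosome 1 or the miR-122 precursor, scaling the precursor shares, and recomputing the windows with the most tags were chosen after seeing the data; the other alternatives were chosen before. Of the recomputed values that answer a comparison, 121 kept their direction and stayed on the same side of their test, within counting error or within 1.5 times, 64 moved, 1 became weaker and 1 reversed. Of 120 recomputed ratios of the 30 leading windows 117 stayed above counting error, 2 became weaker and 1 reversed: lung over liver on chromosome 19 from 9158001 was 0.654 by distinct ends. Of 68 ratios of 17 further windows with the most tags, the same 2 libraries compared, 6 reversed. By distinct ends these were kidney over brain on chromosome 1 from 24618001 (0.517), lung over ovary on chromosome 10 from 80808001 (0.438), kidney over ovary on chromosome 15 from 85536001 (0.307) and spleen over ovary on chromosome 11 from 62416001 (0.542), where few ends were counted; with the trimmed mean of M values they were ovary over lung on chromosome 17 from 39978001 (0.447) and spleen over lung on chromosome 7 from 110974001 (0.870). The cause of these shifts was not tested. The lung to ovary depth ratio was 14.9 by deposited score, 12.1 by listed sequence, 11.4 by distinct end and 16.7 with tags listed at 2 locations kept. Those tags lowered the share of the 10 strongest ends to 9.24% in brain, 5.82% in lung, 9.71% in liver, 9.82% in kidney, 8.96% in ovary and 4.24% in spleen, merging ends within 2 nt raised it to 12.9% in lung, 16.5% in liver, 13.9% in kidney, 10.5% in ovary and 9.24% in spleen, and thinning gave 6.62% in lung. Without the end at 24619958 on chromosome 1 it was 6.78% in brain, 5.60% in lung, 9.89% in liver, 3.31% in kidney and 8.08% in ovary.

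By distinct ends the numbers of led windows were 40 in brain, 97 in lung, 154 in kidney, 12 in ovary and 27 in spleen, and with the trimmed mean of M values, which uses only windows with a tag in both libraries, 663 in lung and 10 in ovary; 873 of the 957 led windows were then led by the same library above counting error. A minimum of 10 tags gave 169 in brain, 377 in kidney, 56 in ovary and 358 in spleen. A minimum of 50 gave 11 in brain, 128 in liver, 111 in kidney, 9 in ovary and 62 in spleen. No minimum gave 609 in brain, 526 in liver, 647 in kidney, 255 in ovary and 724 in spleen. Leaving out 1 library at a time gave 63 to 64 windows in brain, 162 to 315 in lung (315 without ovary), 274 to 303 in liver, 217 to 324 in kidney, 20 to 27 in ovary and 185 to 195 in spleen. Windows of 1 or 5 kb stayed within 1.5 times.

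The lung and ovary correlation was 0.362 thinned, 0.349 with a pseudocount of 0.1 and 0.466 with 10, and that of kidney and spleen -0.056, 0.053 and 0.144. Shared ends of lung and spleen, again as a share of the library with fewer ends, were 30.8% without thinning and 11.9% within 2 nt. Those of brain and kidney were 7.18% and 5.75%. Dominant ends numbered 654 at 10 tags, 191 at 50 tags, 243 at 75% of the window, 933 with tags within 2 nt summed, 133 thinned and 193 to 374 without 1 library (193 without lung). Leaving out libraries gave 60.3% to 74.1% at 3' arm precursor ends, ratios of 357 to 619 after 5' arms and 127 to 1105 tags at microRNA-directed sites (127 without lung). The 9 nt site search, with 269 ends, no longer exceeded the shuffled sets. Weighted by tags, G began 8.31% of brain, 10.5% of liver and 9.18% of kidney tags, and AATAAA lay in 8.82% of lung, 9.73% of liver and 38.2% of spleen tags.

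No paired analysis was possible because each tissue has 1 library. Annotation classes, positions along transcripts, gene list medians and whole gene bodies were not run, since they need an annotation of mm9. The ovary and brain libraries limit what can be seen: a window absent there may still reach 102.7 and 89.9 CPM, and against these limits lung led 125 windows.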

Other observations

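The groups of ends described first, and the test of a strain variant, were chosen after the results were seen; the other tests were chosen before.

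Tags that start within 1 nt of the first base of a mature microRNA numbered 3446 and were distributed differently from those at precursor ends. Mature let-7b starts, at position 85537755 of chromosome 15, reached 5898 CPM in kidney (interval 5530 to 6283), against 2337 in brain and 1917 in ovary, whereas the precursor end of the same hairpin had 943 in kidney. Mature miR-26b starts at position 74440898 of chromosome 1 had 1762 CPM in kidney (interval 1564 to 1979) and 443 in liver. Mature miR-122 starts were found in liver at 2305 CPM (interval 1982 to 2666) and in kidney at 98.6. Over all loci kidney had the largest share of mature starts, 0.934% of its tags (interval 0.887 to 0.982), and spleen the smallest, 0.102% (0.0745 to 0.138).

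A further group of ends lay just before a TGATGA motif, which is the box C element of many small nucleolar RNAs and lies near their 5' end. The motif was most frequent at tag position 7 in every library, with 602 ends there, counted per library, against a median of 273 per position. Ends with the motif at tag positions 6 to 10 after an A or G, matches by coincidence included, held 1.42% of all tags, with 2.40% in spleen (interval 2.26 to 2.55), 1.83% in ovary (1.68 to 1.99), 1.57% in lung (1.54 to 1.61) and 0.738% in brain (0.649 to 0.836), though lung would exceed spleen with the trimmed mean of M values (2.78% against 2.03%). By distinct ends the shares were 0.491% in ovary, 0.442% in spleen, 0.309% in brain, 0.308% in liver, 0.249% in kidney and 0.202% in lung, so spleen did not lead and lung was lowest. The strongest lay at position 62416576 of chromosome 11 (plus strand, TGCAATGATGATGAAACTAG), with 2033 tags, and at position 125626932 of chromosome 8 (plus strand), with 1194. B1 repeats are short interspersed elements transcribed by RNA polymerase III, matched here with up to 4 mismatches to the consensus. Of 537 ends inside sense B1 copies, 37 lay at the first base (6.89%, interval 4.90 to 9.37). The median was 3.5 ends per position, and the next highest position had 17. Of 464 antisense ends, 5 lay at the first base of the reverse complement. That base is opposite the last base of B1, so this is not a count at the same base. The 37 sense ends held 5045 tags, of which 4211 lay at 3 ends with 3 or 4 mismatches. The strongest of these, at position 38320509 of chromosome 18 (minus strand), had 1868 lung tags. All 37 ends together made up 0.948% of the lung tags (interval 0.921 to 0.976) and at most 0.312% elsewhere, in spleen. By distinct ends they were 35 of 270960 in lung and 11 of 25523 in spleen, so lung did not lead. In sense B2 copies 16 of 510 ends (3.14%) lay at the first base, against a median of 3 per position, and another position had 18.

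The low G+C content of the spleen tags was weighed against 3 explanations. It was not confined to a few regions. The 100 windows with the most spleen tags held 27.6% of the spleen tags. Without them, G+C at spleen ends, each counted once, was 31.01%, against 31.3% with them and 44.8% in the lowest other library. This shows only that spleen ends outside these windows are low in G+C too, and a weighting by tags was not tested. Transcription of other regions in spleen cannot be the whole cause either, because within 541 windows shared with lung the median difference, spleen minus lung, was -9.82 percentage points (interval -10.96 to -8.79), below the limit of -7 set before the test. Against kidney it was -13.25 points, also below that limit, but against brain (-6.16), liver (-5.49) and ovary (-4.66) it was not, so the size depends on the library compared, though every interval lay below 0. In 86.7% of the windows shared with lung (interval 83.5 to 89.4) the spleen tags lay 3' of the lung tags, with a median shift of 67.3 nt, which is consistent with spleen tags from nearer the poly(A) tail. Whether this is a property of spleen RNA or of this library's RNA or preparation stays open, since there is 1 spleen library.

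At position 24619958 of chromosome 1 (minus strand), 20652 tags, those listed at 2 locations included, carried 71 different sequences of 20 nt, of which 99.9% of tags differed at 1 base from ATCAACCTGTACACTGTTAT. A strain variant is excluded as the whole cause, because the most common variant held 15.6% of the tags. The positions of the differences followed those at 346 other strong ends (Spearman rho 0.665 over 20 tag positions), as sequencing errors of a single abundant RNA might give. The sequence without a difference has only 14 tags in the tables used here, so its own abundance was not analysed here. The level of this end is therefore likely not comparable with that of other ends, and no biological explanation was tested.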
